A study of Homo sapiens with 24 samples.

How the data were processed

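Total RNA of HCT116 colon cancer cells was measured on 24 Affymetrix 3′ expression arrays, 3 for each of 8 groups formed by cell type (parental or ESR2), oxygen (normoxia or hypoxia) and estradiol (none or 10 nM). Per the labels, ESR2 cells carry a HaloTag fusion of full-length ESR2 delivered by lentivirus and were selected with puromycin, and hypoxia was made by flushing the incubator with nitrogen and CO2. Estradiol was given in phenol-red-free medium with stripped serum, per the labels; the medium of the untreated groups, the length of the hypoxia and a vector control are not given in the sources used here. RNA integrity numbers lay between 8.5 and 10, per the labels' protocols.

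The deposited values are log2 signals made by the authors with RMA, which corrects background, quantile-normalizes the arrays and sums up each probe set; affy and RMA are named per the submitters' processing notes, and their versions are not given in the sources used here. Array medians lay between 4.07 and 4.13. Their upper quartiles lay between 6.34 and 6.60, so that the distributions of the summed values were close but not equal. Quantile normalization of the probes removes much of a shift of most genes at once. RMA compresses changes of dim genes, and the signal of probes far from the 3′ end depends on the length of the labelled RNA.

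The table holds 49386 probe sets, of which 93 are Affymetrix controls. Of the other 49293, 45253 have 1 gene symbol in GEO's platform annotation, 1327 have several and 2713 have none here; no gene was named from the latter kinds. Symbols were checked through Entrez IDs against the RefSeq gene table of GRCh38.p14, which updated 0 and lacked the IDs of 81 probe sets. That table was used only for names and for the genomic span of genes. For each of 18239 genes the probe set with the highest mean over all arrays was used (11822 genes have more than 1), with no filter on dim genes.

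A linear model with a mean for each group was fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes with no trend and no robust prior) in R 4.3.3, with 16 residual degrees of freedom, so that groups of 3 share an estimate of the spread. Tables were handled with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9. The 15 comparisons were hypoxia in parental and in ESR2 cells, ESR2 against parental cells in normoxia and in hypoxia and their interaction, each without and with estradiol, and estradiol in each of 4 settings with its interaction with ESR2 averaged over oxygen. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Errors of fold changes are limma's SE and those of group means the SD.

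Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 25 lists within a comparison. They cover HIF targets, glycolysis, oxidative phosphorylation, DNA replication, mitosis, p53 targets, ATF4 and amino acid stress, ER chaperones, cholesterol synthesis, fatty acid synthesis, NF-kB and cytokines, type I interferon response, MYC and ribosome biogenesis, Wnt targets, estrogen response, immediate early and MAPK feedback genes, NRF2 targets, metallothioneins, heat shock, epithelial-mesenchymal genes, epithelial junctions and keratins, and enterocyte and goblet differentiation. Markers of fibroblasts, of leukocytes and of embryonic kidney lines stand for other cells. Listed genes without a measurement are not analysed here. Groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. Exceptions are the alternatives named as added and the tests named below as chosen after the result was seen.

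Named genes are the 10 with the largest rise and the 10 with the largest fall among those past the threshold with non-overlapping groups, which chance gives to 10% of genes for 3 against 3; interactions need the threshold alone. In estradiol comparisons and those with estradiol the number is 5 and 5. For each list up to 4 members with the smallest p are named, and ESR2, ESR1, ESRRA, GPER1, HIF1A, EPAS1, ARNT, HIF1AN, VHL and EGLN1 could be named anywhere. MYC and EFNA1 in hypoxic parental cells and MYC and LOX in hypoxic ESR2 cells were chosen after their values were seen.

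The alternatives were quantile normalization again, arrays centred on their medians, leaving out the dimmest genes (1 in 3, by mean signal), the mean of a gene's probe sets, every probe set, an intensity trend with a robust prior, array weights, a spread from only the groups compared, the replicate number as a block, leaving out each array in turn, and an estimated correlation in camera. Added after the data were seen were the 3′ minus 5′ index of control probe sets (the mean over beta-actin and the dap and thr spike-ins) as a covariate, that covariate without replicate 2 of parental normoxia, and leaving out the arrays that stand apart. Those are replicate 2 of parental normoxia and, where it is not compared, the hypoxic ESR2 group with estradiol.

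The steps were tested on simulated data with 200 changed genes among 18239. For hypoxia in parental cells, limma recovered 79.1% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 100% of those changed by 2. For the interaction of hypoxia and ESR2 these were 46.3%, 92.5% and 100%, with 12 false calls in each. A simulated shift of the glycolysis list by 0.5 was recovered in both comparisons, with 0 other lists called. The simulated genes were drawn independently of each other, so false list calls among correlated genes were not tested. The real comparisons called a far larger share of genes, 37.5% and 30.7%, and the simulated noise was normal with no array that stands apart. The recovered shares hold for the simulated setting only.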

Results

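Gene expression was measured on 24 Affymetrix arrays from HCT116 cells, an established human colon cancer line. Parental cells and cells transduced with the gene of estrogen receptor beta (ESR2 cells) were each kept in normoxia or hypoxia, and each condition was sampled without and with 10 nM 17β-estradiol, the main natural estrogen. The 8 groups hold 3 arrays each. The values are RMA log2 signals, and 18239 genes were tested. The series asks whether estrogen receptor beta alters how colorectal cancer cells respond to hypoxia. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision.

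Arrays of one group were close to each other. Outside parental normoxia without estradiol their lowest correlation across probe sets was 0.9956. In that group replicate 2 correlated with the other two arrays at 0.988 and 0.989. The difference between 3′ and 5′ control probe sets, which grows when the labelled RNA is shorter, was also large on that array. For the dap spike-in transcript, a bacterial RNA added before labelling, it was 4.46 on the log2 scale on replicate 2 of parental normoxia. In the hypoxic ESR2 group with estradiol it was 3.57 ± 0.16 (SD, n = 3), against 2.03 ± 0.03 (SD, n = 3) in the same cells in hypoxia without estradiol. The 5′ probe set of 18S ribosomal RNA read 11.1 ± 0.08 in the former group and 12.5 ± 0.01 in the latter (SD, n = 3). That of 28S ribosomal RNA went the other way, at 12.31 ± 0.17 and 11.09 ± 0.26 (SD, n = 3). On replicate 2 of parental normoxia both were low, at 7.51 for 18S and 9.82 for 28S. The 3′ minus 5′ difference of GAPDH was 0.74 on that array and 0.04 ± 0.05 (SD, n = 3) in the hypoxic ESR2 group with estradiol. These arrays therefore do not share 1 control profile.

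**Figure D1:**
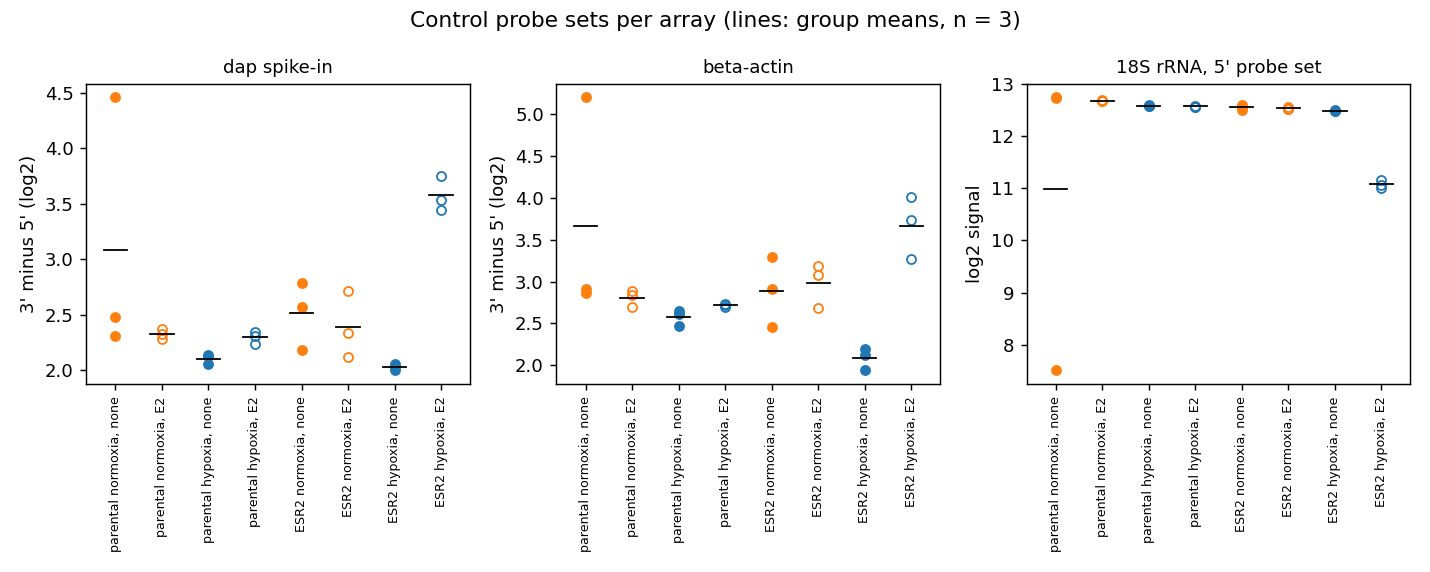
Control probe sets on each of the 24 arrays by group, with the 3′ minus 5′ difference in log2 units for the dap spike-in and beta-actin, and the log2 signal of the 5′ probe set of 18S ribosomal RNA; points are arrays, lines are group means (n = 3), and open points are arrays with estradiol (E2). Replicate 2 of parental normoxia (dap difference 4.46) and the 3 hypoxic ESR2 arrays with estradiol (mean 3.57) lie above the other arrays in the dap panel.

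The transduced gene was examined first. ESR2, measured by its brightest probe set, was 3.47 ± 0.11 in parental and 4.51 ± 0.44 in ESR2 cells in normoxia (log2 signal, SD, n = 3), a rise of 1.04 (SE 0.13; limma, adjusted p = 6.44e-06). In hypoxia it was 3.43 ± 0.11 in parental and 4.07 ± 0.11 in ESR2 cells, a rise of 0.64 (limma, adjusted p = 0.000411). The parental signals lie below the array medians, where changes are compressed, so both rises may be underestimates. Of the 8 probe sets of ESR2, 4 were higher in ESR2 cells in normoxia by 0.93 to 1.36, and the other 4 differed by -0.11 to 0.09. ESR1, the gene of estrogen receptor alpha, lay at 4.04 ± 0.01 in parental and 3.93 ± 0.09 in ESR2 cells in normoxia, with no call.

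The first comparison asks what hypoxia did to parental cells. DDIT4, an inhibitor of mTORC1 signalling, rose 28.5-fold (log2 4.83, SE 0.13; limma, adjusted p = 7.91e-18), and ANKRD37, a target of hypoxia-inducible factor (HIF), rose 26.5-fold (log2 4.73, SE 0.08; adjusted p = 1.39e-21), each with n = 3 per group. ADM, which encodes the vasodilator peptide adrenomedullin, rose 25.3-fold and NDRG1, a stress-responsive gene, 21.6-fold. CXCR4, a chemokine receptor, rose 14.8-fold. ANGPTL4, an inhibitor of lipoprotein lipase, COL13A1, a transmembrane collagen, CCNG2, an atypical cyclin, RSRP1 and BHLHE40, a transcriptional repressor, rose 8.67-fold to 11.5-fold. The genes with the largest falls were MAT2A, which makes S-adenosylmethionine (8.77-fold lower, log2 -3.13, SE 0.09; adjusted p = 9.56e-18), NCOA5, a nuclear receptor coactivator (7.83-fold), SLC35G1 (7.59-fold) and FSAF1 (7.47-fold). CYREN, TOE1, PSPC1, WDR73, EIF5 and POP1 fell 5.32-fold to 5.91-fold; EIF5 is a translation initiation factor and POP1 a subunit of ribonuclease P.

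By gene list, 31 of 37 measured HIF targets rose in hypoxic parental cells, 1 fell and 5 did not pass (31 and 1 adjusted over the list alone, median log2 1.72, camera, adjusted p = 3.16e-29). Camera calls hold with an estimated correlation wherever no p with an estimated correlation is given. The member that fell, EFNA1 (-0.31, SE 0.11; limma, adjusted p = 0.0322), is named after its values were seen, and its call ends under 7 alternatives. Of 22 glycolysis genes 20 rose, 2 did not pass, and 20 rose adjusted over the list alone (median 0.81, camera, adjusted p = 2.95e-17). Among them SLC2A1, the main glucose transporter, rose by 2.85 (SE 0.08), PDK1, a kinase that inhibits pyruvate dehydrogenase, by 2.61 (SE 0.09), ALDOC, an aldolase, by 2.51 (SE 0.06) and HK2, a hexokinase, by 1.93 (SE 0.07). Of 34 genes of the MYC and ribosome biogenesis list 32 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone (median -0.87, camera, adjusted p = 1.32e-17). The ribosome assembly factors RRS1 (-2.05, SE 0.09), NOP2 (-1.96, SE 0.08), MRTO4 (-1.51, SE 0.07) and NIP7 (-1.33, SE 0.06) fell. The member that rose was MYC itself, by 0.32 (SE 0.07; limma, adjusted p = 0.000256), named after its values were seen. Of 41 DNA replication genes 31 fell and 10 did not pass, also adjusted over the list alone (median -0.42, camera, adjusted p = 4.46e-11). Among those that fell were GINS3 (-1.54, SE 0.07), GINS4 (-1.35, SE 0.07) and ORC6 (-1.28, SE 0.07), parts of the replication machinery, and CCNE1 (-1.23, SE 0.07), a cyclin of S-phase entry.

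Further lists rose in hypoxic parental cells. Among 27 epithelial junction and keratin genes 17 rose, 2 fell and 8 did not pass (18 and 2 adjusted over the list alone, median 0.42, camera, adjusted p = 3.57e-06). Examples are CDH1, which encodes E-cadherin (2.04, SE 0.12), ESRP1, an epithelial splicing factor (1.29, SE 0.09), CLDN4, a tight junction claudin (1.23, SE 0.09), and DSC2, a desmosomal cadherin (1.15, SE 0.08). Among 20 cholesterol synthesis genes 11 rose and 9 did not pass (13 rose and 1 fell adjusted over the list alone, median 0.26, camera, adjusted p = 0.000983), with INSIG1, a sterol sensor, up by 1.45 (SE 0.08) and MSMO1, a sterol oxidase, by 1.30 (SE 0.06). Of 29 immediate early and MAPK feedback genes 16 rose, 6 fell and 7 did not pass (17 and 7 adjusted over the list alone, median 0.47, camera, adjusted p = 0.000287). That call is lost at adjusted p = 0.297 with an estimated correlation. Its members DUSP5, DUSP6 and DUSP4, phosphatases of MAP kinases, rose by 1.64 (SE 0.08), 1.42 (SE 0.08) and 1.38 (SE 0.06). Of 23 epithelial-mesenchymal genes 9 rose, 2 fell and 12 did not pass, with the same counts adjusted over the list alone (median 0.15, camera, adjusted p = 0.0219). PLAUR, the urokinase receptor, rose by 2.50 (SE 0.07), FN1, fibronectin, by 2.02 (SE 0.17) and VIM, vimentin, by 0.99 (SE 0.08). Of 26 ER chaperone genes 12 rose, 7 fell and 7 did not pass (13 and 8 adjusted over the list alone, median 0.17, camera, adjusted p = 0.0351, and adjusted p = 0.277 with an estimated correlation); DNAJB9 rose by 1.43 (SE 0.11).

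The estrogen response list also moved in parental cells with no estradiol added: 10 of 30 rose, 3 fell and 17 did not pass, with the same counts adjusted over the list alone (median 0.12, camera, adjusted p = 0.0241, and adjusted p = 0.0935 with an estimated correlation). Its leading members, STC2 (2.45, SE 0.08) and CA12 (1.72, SE 0.12), a secreted glycoprotein and a carbonic anhydrase, are members of the HIF target list as well; PKIB, a protein kinase A inhibitor, rose by 1.97 (SE 0.16). Of the oxygen-sensing genes, EGLN1, the main HIF prolyl hydroxylase, rose by 1.41 (SE 0.10) and EPAS1, HIF-2α, by 0.90 (SE 0.09). HIF1A, HIF-1α, fell by 0.50 (SE 0.09; limma, adjusted p = 7.41e-05), a call that ends with the mean of its probe sets (-0.41; adjusted p = 0.0978). In all, limma called 6844 genes for hypoxia in parental cells, 2983 higher and 3861 lower, of which 456 and 608 passed 2-fold. The estrogen response call also ends with the mean of probe sets (adjusted p = 0.0557), and that of ER chaperones with only the groups compared (0.0573) or without parental normoxia replicate 3 (0.0543).

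In ESR2 cells hypoxia raised genes that also led in parental cells. CXCR4 rose 11.2-fold (log2 3.48, SE 0.11; limma, adjusted p = 2.03e-16), ANKRD37 9.91-fold, NDRG1 9.57-fold, DDIT4 8.83-fold and ADM 8.62-fold, with n = 3 per group. SLC2A1, P4HA1, a collagen prolyl hydroxylase, WFDC3, ANGPTL4 and ARPC3, a subunit of the actin-nucleating Arp2/3 complex, rose 5.22-fold to 6.12-fold. The largest falls were those of CXCL10, an interferon-inducible chemokine (4.31-fold lower, log2 -2.11, SE 0.13; adjusted p = 3.15e-11), MAL2, a transport protein of epithelial cells (3.75-fold), RPL27A, a ribosomal protein (3.68-fold), and IFIT2, an interferon-induced gene (3.52-fold). CRACR2A, BST1, DLEU2, FBXO4 and CMTM1 fell 2.98-fold to 3.45-fold. HIF1A fell 3.30-fold, from 10.4 ± 0.10 to 8.65 ± 0.12 (log2 signal, SD, n = 3).

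Of 37 HIF targets 31 rose in hypoxic ESR2 cells, 1 fell and 5 did not pass (32 and 1 adjusted over the list alone, median 1.17, camera, adjusted p = 2.57e-35); KDM3A, a histone demethylase, rose by 2.02 (SE 0.07). The member that fell was LOX, a collagen cross-linking enzyme (-0.45, SE 0.10; limma, adjusted p = 0.000714). It is named after its values were seen, and with the mean of its probe sets its adjusted p is 0.106. All 22 glycolysis genes rose, also adjusted over the list alone (median 0.88, camera, adjusted p = 3.85e-26), with ALDOC up by 1.97 (SE 0.06) and GPI, the isomerase of glucose 6-phosphate, by 1.65 (SE 0.07). EGLN1 rose by 1.31 (SE 0.10) and EPAS1 by 0.81 (SE 0.09). Of 29 immediate early genes 22 rose, 2 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.58, camera, adjusted p = 2.66e-14). Examples are CCN1, a matricellular growth regulator (2.35, SE 0.15), and DUSP5 (1.34, SE 0.08). Of 27 epithelial junction and keratin genes 15 rose and 12 did not pass, also adjusted over the list alone (median 0.24, camera, adjusted p = 3.59e-07), among them CDH1 (1.34, SE 0.12), ELF3, an epithelial transcription factor (1.27, SE 0.10), and KRT18 (0.78, SE 0.06). Of 23 epithelial-mesenchymal genes 9 rose, 4 fell and 10 did not pass, also adjusted over the list alone (median 0.12, camera, adjusted p = 0.00435), with VIM up by 1.62 (SE 0.08) and SNAI2, a transcription factor of mesenchymal change, by 1.38 (SE 0.08).

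Heat shock genes rose in hypoxic ESR2 cells, 10 of 19 with 9 not passing, also adjusted over the list alone (median 0.41, camera, adjusted p = 0.0002). SERPINH1, a collagen chaperone, rose by 2.07 (SE 0.12) and BAG3, a co-chaperone, by 0.57 (SE 0.07). Of 22 Wnt and beta-catenin targets 10 rose and 12 did not pass (11 rose and 1 fell adjusted over the list alone, median 0.13, camera, adjusted p = 0.00782), including CD44, BAMBI and AXIN2, the last a negative regulator of the pathway (0.95, SE 0.07; 0.95, SE 0.11; 0.66, SE 0.10). Of 30 estrogen response genes 10 rose, 4 fell and 16 did not pass (13 and 4 adjusted over the list alone, median 0.10, camera, adjusted p = 0.00478); STC2 rose by 2.02 (SE 0.08) and RET, a receptor tyrosine kinase, by 1.81 (SE 0.14). Ribosome biogenesis genes fell, 21 of 34 with 1 rise and 12 not passing (25 and 1 adjusted over the list alone, median -0.33, camera, adjusted p = 2.04e-07). NOP16 (-0.75, SE 0.08), SRM, spermidine synthase (-0.68, SE 0.08), and MRTO4 (-0.67, SE 0.07) fell, while MYC rose by 0.24 (SE 0.07). Of 20 cholesterol genes 10 fell, 1 rose and 9 did not pass (12 and 1 adjusted over the list alone, median -0.23, camera, adjusted p = 0.0264). HMGCS1, an early enzyme of the pathway (-1.05, SE 0.10), and HSD17B7 (-0.66, SE 0.09) fell, and TM7SF2, a sterol reductase, rose by 0.92 (SE 0.09). Oxidative phosphorylation genes fell, 18 of 38 with 3 rises and 17 not passing (20 and 3 adjusted over the list alone, median -0.16, camera, adjusted p = 0.00625, and adjusted p = 0.314 with an estimated correlation); NDUFB10 and NDUFV2, of respiratory complex I, had -0.44 (SE 0.08) and -0.43 (SE 0.06). DNA replication genes were not called as a list (5 rose, 13 fell and 23 did not pass; 5 and 14 adjusted over the list alone, median -0.04, camera, adjusted p = 0.751).

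For hypoxia in ESR2 cells limma called 5940 genes, 2620 higher and 3320 lower, with 225 and 93 past 2-fold. Of genes called for hypoxia in both kinds of cells, 1319 rose in both, 1516 fell in both and 743 went opposite ways, where independent lists would share 429 and 703; these comparisons share no arrays. The Pearson correlation of the changes across genes was 0.44, and genes are not independent replicates. The cholesterol call ends when every probe set is tested (adjusted p = 0.0628) or when hypoxic ESR2 replicate 3 is left out (adjusted p = 0.0502), and the estrogen response call ends when every probe set is tested (adjusted p = 0.058).

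**Figure D2:**
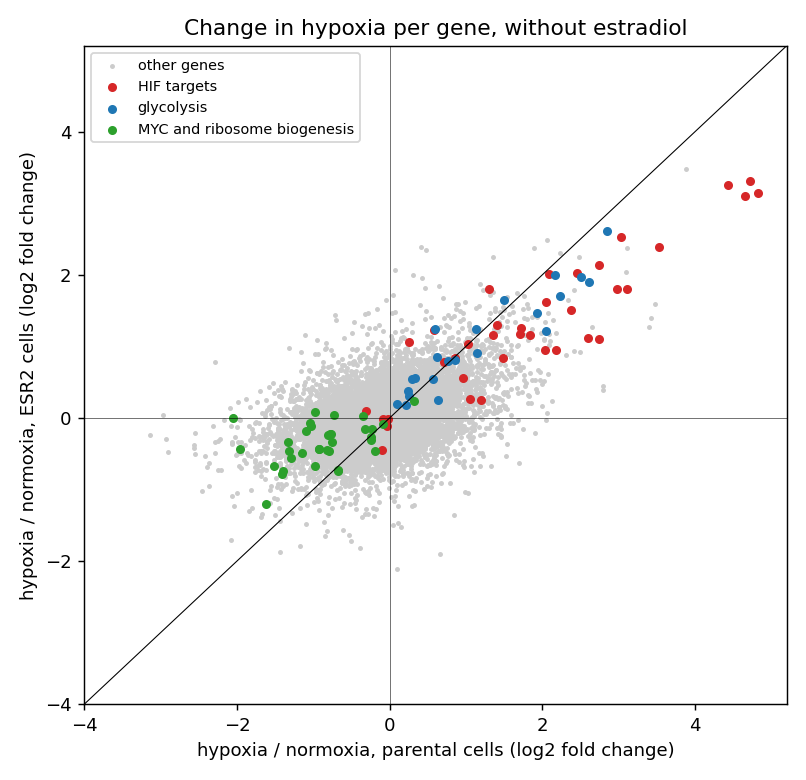
Change in hypoxia per gene without estradiol, as log2 fold change in parental cells (x axis) and in ESR2 cells (y axis), n = 3 arrays per group; each point is a gene, with HIF targets, glycolysis genes and the MYC and ribosome biogenesis list in colour and the diagonal marking equal change. Glycolysis genes have list means of 1.16 and 1.06 in the parental and ESR2 cells, HIF targets 1.88 and 1.32, and ribosome biogenesis genes -0.89 and -0.35.

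Whether the hypoxia change differed between ESR2 and parental cells was tested as an interaction, ESR2 minus parental. The ribosome biogenesis and DNA replication genes, which fell in parental cells, had a positive interaction. Of 34 ribosome biogenesis genes 22 were higher and 12 did not pass (22 higher and 1 lower adjusted over the list alone, median 0.52, camera, adjusted p = 1.1e-09), as for RRS1 (2.06, SE 0.12; limma, adjusted p = 3.31e-11) and NOP2 (1.52, SE 0.12). Of 41 DNA replication genes 24 were higher, 1 was lower and 16 did not pass (29 and 2 adjusted over the list alone, median 0.38, camera, adjusted p = 1.1e-09), as for GINS4 (1.47, SE 0.10) and CCNE1 (1.31, SE 0.09). Of 20 cholesterol synthesis genes 12 were lower, 1 was higher and 7 did not pass, also adjusted over the list alone (median -0.54, camera, adjusted p = 4.2e-06), as for INSIG1 (-1.69, SE 0.11) and MSMO1 (-1.44, SE 0.08).

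HIF targets had a negative interaction in 23 of 37 members, a positive one in 3 and none past the threshold in 11 (23 and 4 adjusted over the list alone, median -0.51, camera, adjusted p = 1.46e-07, and adjusted p = 0.0836 with an estimated correlation). HILPDA, a lipid droplet protein, had -1.64 (SE 0.12) and ANKRD37 -1.42 (SE 0.12). HIF1A had -1.22 (SE 0.13; limma, adjusted p = 1.15e-07). Glycolysis genes were not called (6 lower and 16 not passing; 6 lower and 1 higher adjusted over the list alone, median -0.02, camera, adjusted p = 0.419). Of 19 heat shock genes 9 were higher, 2 lower and 8 did not pass (11 and 2 adjusted over the list alone, median 0.39, camera, adjusted p = 0.0066, and adjusted p = 0.0836 with an estimated correlation); SERPINH1 had 2.00 (SE 0.16) and DNAJA1, a co-chaperone, 1.22 (SE 0.11). The mean hypoxia change of ESR2 cells divided by that of parental cells was 0.705 (SE 0.0373) for HIF targets, 0.914 (SE 0.0617) for glycolysis, 0.398 (SE 0.0508) for ribosome biogenesis and 0.0599 (SE 0.037) for DNA replication.

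The single genes with the largest positive interaction were DIDO1 (3.08, SE 0.18; limma, adjusted p = 2.76e-11), NCOA5 (3.02), MAT2A (2.90), SLC35G1 (2.63), FSAF1 (2.43) and WDR73 (2.34), followed by CCDC71, DLX2, CEBPA, a differentiation factor, and RDH10, a retinol dehydrogenase, at 2.21 to 2.29. The largest negative ones were those of MAL2 (-2.57, SE 0.23; adjusted p = 1.62e-08), OSMR, the oncostatin M receptor (-2.41), KLF9, a transcription factor (-2.35), LCORL (-2.33), CXCL10 (-2.21) and ZNF226 (-2.20), with RSRP1, TRIOBP, GASK1B and KRTAP4-9 at -2.13 to -2.07. limma called 5597 genes, 2987 with a positive and 2610 with a negative interaction. Of these, 580 and 307 passed 2-fold. The heat shock call ends without the dimmest genes (adjusted p = 0.0737).

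In normoxia, ESR2 cells differed from parental cells in p53 targets and interferon-response genes. The ESR2 cells were also transduced by lentivirus and selected with puromycin, and no vector control is given. In all comparisons of the cells these cannot be told apart from ESR2 itself. GDF15, a stress cytokine and p53 target, was 9.59-fold higher in ESR2 cells (log2 3.26, SE 0.16, limma, adjusted p = 3.01e-12). Its log2 signal in these parental cells lay between 3.07 and 3.81, below the array medians, so the fold change may be an underestimate. MAL2 was 12.2-fold, GASK1B 11.0-fold, SMARCA1, a chromatin remodeller, 8.81-fold, TP53INP1, a p53 target, 4.85-fold and CXCL10 4.49-fold higher, with n = 3 per group. PDE4B, a phosphodiesterase of cyclic AMP, ADIRF, DIRAS3 and TRIM2, a ubiquitin ligase, rose 3.34-fold to 3.78-fold. NT5E, the ectonucleotidase CD73, was 4.13-fold lower (log2 -2.05, SE 0.16; adjusted p = 4.86e-09), DCLK1, a kinase, 3.02-fold and GPAT2 2.96-fold. FOSL1, SYTL3, CCN1, CSTA, a protease inhibitor, KLF10, BCAR3 and F3, tissue factor, were 2.05-fold to 2.39-fold lower.

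Of 26 p53 targets 16 were higher in normoxic ESR2 cells, 2 lower and 8 did not pass (18 and 2 adjusted over the list alone, median 0.40, camera, adjusted p = 1.23e-11); CDKN1A, the cell cycle inhibitor p21, was higher by 1.43 (SE 0.10) and TP53I3 by 1.29 (SE 0.10). Of 35 type I interferon response genes 13 were higher and 22 did not pass (14 adjusted over the list alone, median 0.14, camera, adjusted p = 1.17e-06). IFIH1, a sensor of double-stranded RNA, was higher by 1.61 (SE 0.18), IFIT2 by 1.32 (SE 0.12), IFIT3 by 1.30 (SE 0.12) and IFIT1 by 1.09 (SE 0.08). Of 23 NRF2 targets 9 were higher and 14 did not pass (10 higher and 1 lower adjusted over the list alone, median 0.13, camera, adjusted p = 0.00118), with NQO1, a quinone reductase, at 0.97 (SE 0.06), ABCC2, an efflux pump, at 0.93 (SE 0.08) and PGD at 0.77 (SE 0.11). Of 31 ATF4 and amino acid stress genes 14 were lower, 1 higher and 16 did not pass (19 and 1 adjusted over the list alone, median -0.20, camera, adjusted p = 3.03e-06); DDIT3, the stress factor CHOP, had -0.95 (SE 0.12) and TRIB3 -0.44 (SE 0.07).

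Other lists called for ESR2 in normoxia were lost with an estimated correlation. Of 29 immediate early genes 17 were lower, 2 higher and 10 did not pass (18 and 2 adjusted over the list alone, median -0.42, camera, adjusted p = 2.41e-06, and adjusted p = 0.138 with an estimated correlation). DUSP4 fell by 0.43 (SE 0.06), while EREG, an EGF receptor ligand, rose by 1.12 (SE 0.11). Of 41 DNA replication genes 12 were lower, 1 higher and 28 did not pass (14 and 2 adjusted over the list alone, median -0.14, camera, adjusted p = 0.0147, and adjusted p = 0.126 with an estimated correlation), as for UNG, which removes uracil from DNA (-0.68, SE 0.14), and CDC45 (-0.40, SE 0.07). Of 8 metallothioneins 3 were lower and 5 did not pass (4 lower adjusted over the list alone, median -0.17, camera, adjusted p = 0.0147, and adjusted p = 0.171 with an estimated correlation), with MT1F at -0.54 (SE 0.09) and MT2A at -0.17 (SE 0.05). Of 27 epithelial junction genes 9 were higher and 18 did not pass (10 higher and 1 lower adjusted over the list alone, median 0.14, camera, adjusted p = 0.00958, and adjusted p = 0.077 with an estimated correlation); DSC2 rose by 0.92 (SE 0.08) and CDH1 by 0.68 (SE 0.12). HLA-DRA, an antigen-presenting molecule of the leukocyte marker list, rose by 1.46 (SE 0.09), a list not called as a whole (1 higher, 1 lower and 14 not passing, also adjusted over the list alone, median 0.04, camera, adjusted p = 0.443). HIF1A was higher by 0.45 (SE 0.09; limma, adjusted p = 0.00112).

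limma called 3396 genes for ESR2 in normoxia, 1780 higher and 1616 lower, with 57 and 10 past 2-fold. With arrays centred on their medians 1555 were higher and 1908 lower. With a spread estimated from only the groups compared the count is 1061, with array weights, which give replicate 2 of parental normoxia a weight of 0.138, it is 5187, and without the arrays that stand apart it is 2905. Calls end for FOSL1 (adjusted p = 0.118), HIF1A (0.0873) and MT2A (0.175) with only the groups compared, for CDC45 with the mean of its probe sets (-0.04; adjusted p = 0.874), for MT2A also without ESR2 normoxia replicate 2 (adjusted p = 0.0589), for the DNA replication list without parental normoxia replicate 1 (0.106) or 3 (0.0552) and for the metallothioneins without replicate 3 of the same group (0.0764).

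In hypoxia, genes of ribosome biogenesis, DNA replication and the p53 pathway were higher in ESR2 than in parental cells, and cholesterol synthesis genes were lower. DIDO1, a chromatin protein, was 8.31-fold higher (log2 3.06, SE 0.13; limma, adjusted p = 2.09e-14), NCOA5 8.29-fold, GDF15 7.94-fold, MAT2A 7.79-fold and TP53I3 7.50-fold, with n = 3 per group. SLC35G1, FAM200C, LCMT2, FSAF1 and ID2, an inhibitor of differentiation factors, were 5.22-fold to 6.35-fold higher. KLF9 was 8.58-fold lower (log2 -3.10, SE 0.15; adjusted p = 1.19e-13), LCORL 7.75-fold, KRTAP2-3 7.53-fold and OSMR 5.77-fold. TRIOBP, NT5E, ZNF226, ARHGAP11A, LEPR, the leptin receptor, and BRWD1 were 4.12-fold to 5.37-fold lower.

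Of 34 ribosome biogenesis genes 24 were higher in hypoxic ESR2 than in hypoxic parental cells, 4 lower and 6 did not pass (25 and 4 adjusted over the list alone, median 0.47, camera, adjusted p = 7.28e-08), with RRS1 higher by 2.19 (SE 0.09), NOP2 by 1.37 (SE 0.08) and NIP7 by 0.97 (SE 0.06). Of 41 DNA replication genes 23 were higher, 1 lower and 17 did not pass (23 and 2 adjusted over the list alone, median 0.31, camera, adjusted p = 1.76e-07), with CCNE2, a cyclin of S-phase entry, higher by 2.10 (SE 0.13), GINS4 by 1.22 (SE 0.07), CCNE1 by 1.09 (SE 0.07) and ORC6 by 1.02 (SE 0.07). Of 26 p53 targets 17 were higher, 1 lower and 8 did not pass (17 and 3 adjusted over the list alone, median 0.46, camera, adjusted p = 2.18e-06); TIGAR, a regulator of glycolysis, was higher by 1.59 (SE 0.09). Of 19 heat shock genes 9 were higher, 1 lower and 9 did not pass, also adjusted over the list alone (median 0.30, camera, adjusted p = 0.000839), with DNAJA1 at 1.69 (SE 0.08), SERPINH1 at 1.27 (SE 0.12) and HSPA1B, an HSP70 gene, at 0.76 (SE 0.07). Of 20 cholesterol genes 14 were lower, 2 higher and 4 did not pass (15 and 2 adjusted over the list alone, median -0.38, camera, adjusted p = 8.75e-05), with INSIG1 at -1.60 (SE 0.08), MSMO1 at -1.41 (SE 0.06) and DHCR7, a sterol reductase, at -0.88 (SE 0.08). Of 37 HIF targets 26 were lower, 3 higher and 8 did not pass (26 and 5 adjusted over the list alone, median -0.42, camera, adjusted p = 2.38e-07, and adjusted p = 0.0639 with an estimated correlation). HILPDA had -1.62 (SE 0.08), ANKRD37 -1.45 (SE 0.08), NFIL3, a transcriptional repressor, -1.14 (SE 0.08) and MXI1, a MYC antagonist, -1.02 (SE 0.08). HIF1A was lower as well (-0.78, SE 0.09). limma called 7369 genes, 3726 higher and 3643 lower, with 493 and 194 past 2-fold. With quantile normalization again 3397 were higher and 3489 lower. The call of MXI1 ends with the mean of its probe sets (-0.14; adjusted p = 0.257).

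**Figure D3:**
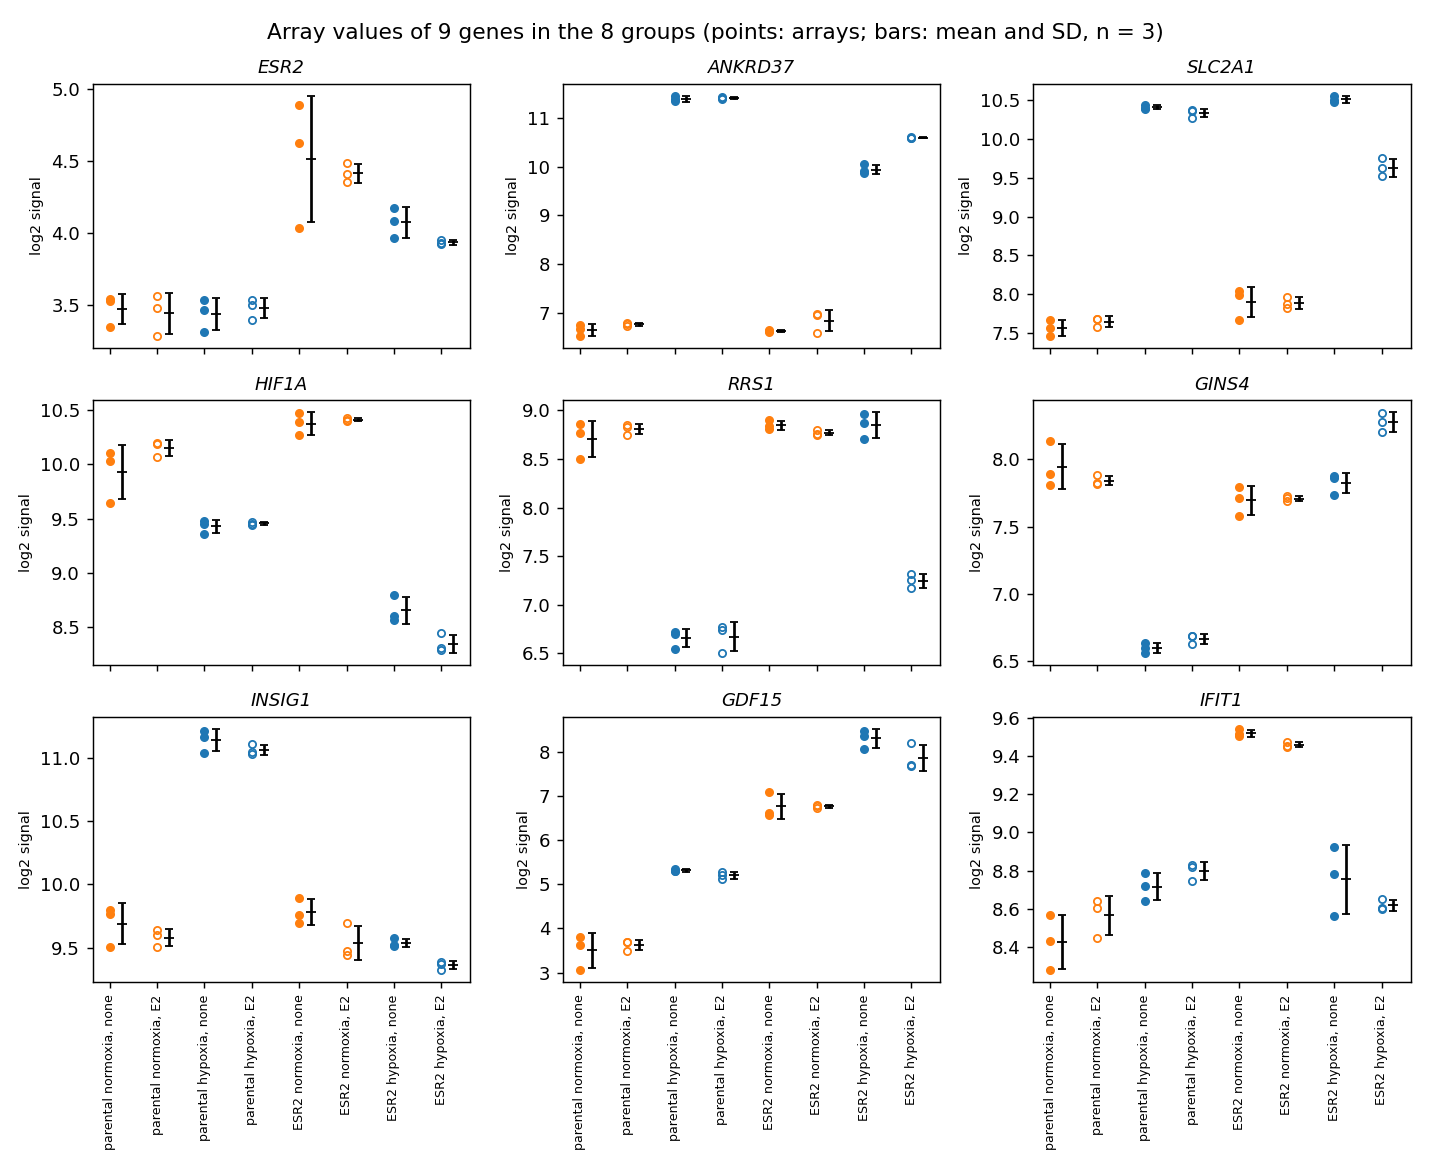
Array values (log2 signal) of 9 genes in the 8 groups; points are arrays, bars are mean and SD (n = 3), and open points are arrays with estradiol (E2). SLC2A1 rose in hypoxia to 10.4 in parental and 10.5 in ESR2 cells without estradiol, while RRS1 fell to 6.66 in hypoxic parental cells and was 8.85 in hypoxic ESR2 cells.

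Estradiol alone changed few genes outside the hypoxic ESR2 group. In parental cells in normoxia MT1F, a metallothionein (-0.57, SE 0.09; limma, adjusted p = 0.0197), and KLC3, a kinesin light chain (-0.47, SE 0.08; adjusted p = 0.0326), were lower, with n = 3 per group; these 2 genes were the only ones called, beside 2524 at an unadjusted p under 0.05. Of 8 metallothioneins 1 fell and 7 did not pass (2 fell adjusted over the list alone, median -0.08, camera, adjusted p = 0.0495), and of 31 ATF4 genes none passed (4 fell adjusted over the list alone, median -0.10, camera, adjusted p = 0.0396), each at adjusted p = 0.836 with an estimated correlation. In parental cells in hypoxia RSRP1 (-1.07, SE 0.13; adjusted p = 0.000383) and KRTAP4-9 (-0.61, SE 0.10) were lower and KIN, a DNA-binding protein, higher by 0.39 (SE 0.07), the 3 genes called beside 846 at an unadjusted p under 0.05. Lists called there had no member past the threshold and small medians: glycolysis -0.05 and mitosis 0.06 (camera, adjusted p = 0.0185 each) and ER chaperones -0.05 (adjusted p = 0.0337), each at adjusted p = 0.631 with an estimated correlation. Adjusted over the list alone, 0 of 22, 0 of 37 and 1 of 26 passed.

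The calls for estradiol in parental cells depended on the setting. KLC3 is not called under 12 alternatives, MT1F and KIN under 10 each, KRTAP4-9 under 6 and RSRP1 under 1, the mean of its probe sets (-0.44; adjusted p = 0.0942). The count in parental normoxia is 0 without replicate 2 of the untreated group and 643 without replicate 1, in both cases by limma. Leaving out 1 array also ends the list calls. In normoxia that of ATF4 genes ends without untreated replicate 1 (adjusted p = 0.0656) or 2 (0.0846) or estradiol replicate 2 (0.0757) or 3 (0.0609), and that of metallothioneins without untreated replicate 1 (0.0656) or 3 (0.363) or estradiol replicate 2 (0.12) or 3 (0.0609). In hypoxia that of glycolysis ends without untreated replicate 1 (0.068) or 2 (0.0586) or estradiol replicate 1 (0.0911) or 3 (0.0512). That of mitosis ends without untreated replicate 1 (0.259) or estradiol replicate 1 (0.119) or 3 (0.105), and that of ER chaperones without untreated replicate 2 (0.254) or 3 (0.0726) or estradiol replicate 1 (0.119) or 3 (0.105).

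In ESR2 cells in normoxia limma called 0 genes for estradiol, beside 981 at an unadjusted p under 0.05. The estrogen response list was nevertheless shifted upward (0 of 30 past the threshold over all genes, 4 higher adjusted over the list alone, median 0.08, camera, adjusted p = 3.44e-05). PKIB had 0.66 (SE 0.16), KRT13, a keratin, 0.38 (SE 0.09), STC2 0.34 (SE 0.08) and TPD52L1 0.21 (SE 0.07), of which PKIB passes with array weights (adjusted p = 0.015) or with only the groups compared (adjusted p = 0.00423). Cholesterol synthesis genes were shifted downward (0 of 20 past the threshold, also adjusted over the list alone, median -0.09, camera, adjusted p = 0.00157), with INSIG1 at -0.24 (SE 0.08), CYP51A1, a sterol demethylase, at -0.21 (SE 0.07) and MSMO1 at -0.17 (SE 0.06). The cholesterol call ends without ESR2 normoxia replicate 2 (adjusted p = 0.0523) or without replicate 1 with estradiol (adjusted p = 0.068).

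In ESR2 cells in hypoxia, with estradiol, AKR1B10, an aldo-keto reductase, was 4.27-fold higher (log2 2.09, SE 0.14; limma, adjusted p = 1.68e-11), IRF7, an interferon regulatory factor, 3.78-fold, and ZNF789, ELL2, a transcription elongation factor, and MAL2 3.38-fold to 3.61-fold higher, with n = 3 per group. ARID1B, a subunit of the SWI/SNF chromatin remodelling complex, was 10.2-fold lower (log2 -3.36, SE 0.10; adjusted p = 9.73e-17), and HIRA, a histone chaperone, GRB10, a growth factor receptor adaptor, FHOD3, a formin, and ZMIZ1 were 6.60-fold to 7.62-fold lower. The same 3 arrays carry the large 3′ minus 5′ differences given above. Of 34 ribosome biogenesis genes 22 fell, 4 rose and 8 did not pass (23 and 4 adjusted over the list alone, median -0.48, camera, adjusted p = 2.85e-06, and adjusted p = 0.148 with an estimated correlation), as for RRS1 (-1.60, SE 0.09), NIP7 (-0.91, SE 0.06), CAD (-0.87, SE 0.07) and MYC (-0.82, SE 0.07). Of 29 immediate early genes 17 fell, 5 rose and 7 did not pass (18 and 5 adjusted over the list alone, median -0.51, camera, adjusted p = 0.00107, and adjusted p = 0.308 with an estimated correlation); KLF6 (-1.08, SE 0.08) and KLF10 (-1.04, SE 0.09) fell, and ATF3, a stress factor, rose by 1.26 (SE 0.09).

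Of 19 heat shock genes 11 fell with estradiol in hypoxic ESR2 cells, 3 rose and 5 did not pass (11 and 4 adjusted over the list alone, median -0.23, camera, adjusted p = 0.00534, and adjusted p = 0.148 with an estimated correlation), with SERPINH1 at -1.54 (SE 0.12), DNAJA1 at -0.80 (SE 0.08) and HSPA8, the constitutive HSP70, at -0.70 (SE 0.05). Of 16 leukocyte markers 11 rose and 5 did not pass, also adjusted over the list alone (median 0.29, camera, adjusted p = 0.0375, and adjusted p = 0.297 with an estimated correlation), led by CD68, a lysosomal glycoprotein (1.68, SE 0.14), and HLA-DRA (0.90, SE 0.09). HIF1A was lower (-0.31, SE 0.09; limma, adjusted p = 0.00636). ESR2 itself had -0.14 with no call (adjusted p = 0.371).

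limma called 10394 genes for estradiol in hypoxic ESR2 cells, 6459 higher and 3935 lower, with 200 and 865 past 2-fold; the median change over all genes was 0.116. Among genes with a mean log2 signal over 6 the called ones were 2184 higher and 2789 lower, and without the dimmest genes they were 4295 and 3858. With the 3′ minus 5′ index of the control probe sets as a covariate, a setting chosen after the data were seen, the calls number 6897 (46.6% higher, against 62.1%), and 4092 when replicate 2 of parental normoxia is also left out. HIF1A is called under neither (-0.015 and -0.271, limma, adjusted p = 0.934 and 0.264), and ESR2 is called only under the latter (-0.85, adjusted p = 0.0319). With the covariate heat shock (median -0.182, camera, adjusted p = 0.114) and leukocyte markers (median 0.211, adjusted p = 0.0599) are not called. Quantile normalization ends the leukocyte call (0.131), as does leaving out hypoxic ESR2 replicate 2 without (0.065) or replicate 1 with estradiol (0.0618), and the mean of probe sets ends that of DNAJA1 (-0.09; adjusted p = 0.161).

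The change with estradiol followed the genomic span of the gene in hypoxic ESR2 cells. Among 7189 genes with a mean log2 signal over 6, the median change was 0.08 for 1464 genes up to 10 kb, 0.00 for 3328 genes of 10 to 50 kb and -0.11 for 1243 genes of 50 to 100 kb. It was -0.31 for 803 genes of 100 to 200 kb, -0.60 for 269 genes of 200 to 400 kb and -0.96 for 82 genes over 400 kb. Spearman's rho across these genes was -0.248, and genes are not independent replicates. In the other 3 estradiol comparisons rho had the opposite sign, at 0.285 in parental normoxia, 0.24 in parental hypoxia and 0.155 in ESR2 normoxia. Every median by span in these 3 lay between -0.07 and 0.04. With the 3′ minus 5′ covariate and without replicate 2 of parental normoxia, those of parental normoxia lay between -0.02 and 0.02. Long genes were also lower in ESR2 than in parental cells in hypoxia without estradiol. There the median was 0.09 for genes up to 10 kb and -0.41 for genes over 400 kb. The interaction of hypoxia and ESR2 without estradiol had a median of -0.5 for genes over 400 kb.

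**Figure D4:**
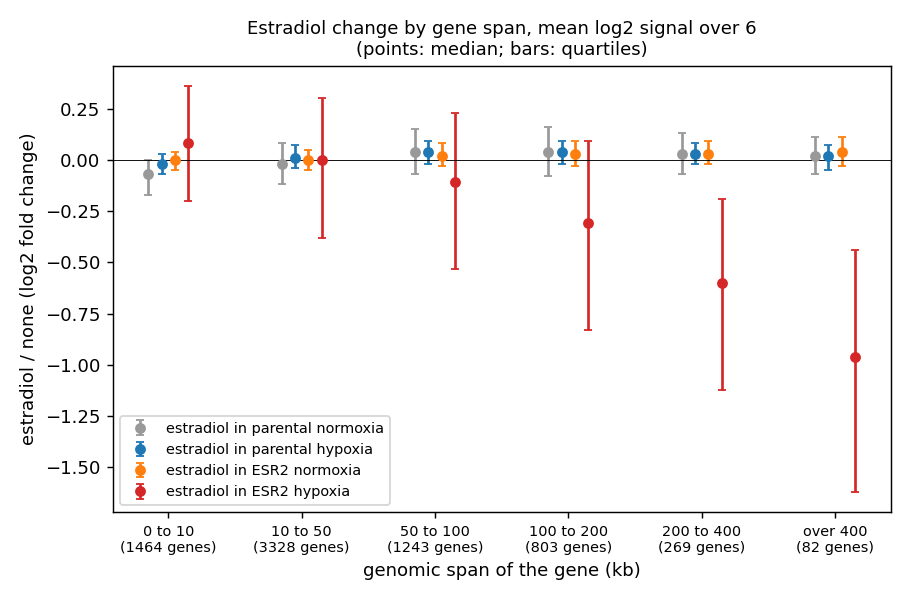
Change with estradiol (log2 fold change, y axis) by the genomic span of the gene in kb (x axis) for genes with a mean log2 signal over 6; points are medians over the genes of a bin, bars are quartiles, and colours are the 4 estradiol comparisons (n = 3 arrays per group). In hypoxic ESR2 cells the median falls from 0.08 for genes up to 10 kb to -0.96 for genes over 400 kb.

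The estradiol change of ESR2 cells minus that of parental cells, averaged over normoxia and hypoxia, was called in 4460 genes, 2109 positive and 2351 negative. With quantile normalization again 2583 were positive and 2030 negative. Estradiol alone called 10394 genes in hypoxic ESR2 cells, 0 in normoxic ESR2 cells, and 2 and 3 in parental normoxia and hypoxia. The difference therefore rests mainly on the hypoxic ESR2 arrays with estradiol, which have the high 3′ minus 5′ index. The largest positive values were those of AKR1B10 (1.27, SE 0.14; limma, adjusted p = 5.71e-07), IRF7 (1.08), VWA5A (1.03), CD68 (1.02) and ABHD14B (1.01), and the largest negative ones those of HIRA (-1.87, SE 0.30; adjusted p = 5.63e-05), ARID1B (-1.68), LMNB1, a lamin (-1.58), GRB10 (-1.48) and MAGOHB (-1.37). Ribosome biogenesis genes were lower in 19 of 34, higher in 2 and did not pass in 13 (20 and 2 adjusted over the list alone, median -0.31, camera, adjusted p = 3.54e-07, and adjusted p = 0.132 with an estimated correlation). Immediate early genes were lower in 11 of 29, higher in 4 and did not pass in 14 (12 and 4 adjusted over the list alone, median -0.17, camera, adjusted p = 0.0153, and adjusted p = 0.448 with an estimated correlation). Heat shock genes were lower in 9 of 19, higher in 2 and did not pass in 8 (11 and 2 adjusted over the list alone, median -0.19, camera, adjusted p = 0.0153, and adjusted p = 0.193 with an estimated correlation). Without replicate 2 of parental normoxia and with the 3′ minus 5′ index as a covariate 2870 genes are called, and neither the immediate early (adjusted p = 0.0667) nor the heat shock list (0.0667). Without the dimmest genes both calls end (0.141 and 0.0927), as does that of heat shock with the covariate on all arrays (0.135) and that of immediate early genes without hypoxic ESR2 replicate 1 (0.0806).

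With estradiol present in both conditions, hypoxia in parental cells raised DDIT4 27.0-fold (log2 4.75, SE 0.13; limma, adjusted p = 1.44e-17), ANKRD37 24.8-fold, NDRG1 23.5-fold, ADM 22.1-fold and CXCR4 14.6-fold and lowered MAT2A 8.18-fold, SLC35G1, TOE1, NCOA5 and FSAF1 5.47-fold to 7.29-fold, with n = 3 per group. limma called 6345 genes, 2933 higher and 3412 lower; 5493 were called with and without estradiol, 2391 higher and 3102 lower in both, and none in opposite directions. In ESR2 cells with estradiol, hypoxia raised WFDC3 14.7-fold (log2 3.88, SE 0.13; adjusted p = 2.45e-16), ANKRD37 13.4-fold, CXCR4 11.1-fold, NDRG1 10.3-fold and P4HA1 8.28-fold, and lowered ARID1B 10.5-fold, FBXO4 9.05-fold, NSMCE2, a SUMO ligase, 8.02-fold, RABGAP1L 7.33-fold and CALML4 7.26-fold. Here 9534 genes were called, 5407 higher and 4127 lower, and of 4047 called in ESR2 cells with and without estradiol 971 went opposite ways.

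ESR2 cells against parental cells in normoxia with estradiol again had higher GASK1B (11.3-fold, log2 3.50, SE 0.15; limma, adjusted p = 3.42e-13), MAL2, GDF15, SMARCA1 and TP53INP1 (5.69-fold to 10.0-fold) and lower NT5E, DCLK1, GPAT2, F3 and SYTL3 (2.41-fold to 4.06-fold), with n = 3 per group. limma called 2494 genes, 1542 higher and 952 lower, and 3772 with a spread from only the groups compared or 4437 with array weights. In hypoxia with estradiol TP53I3 was 25.6-fold higher (log2 4.68, SE 0.10; adjusted p = 1.51e-19), CCNE2 12.0-fold, EPM2AIP1 10.2-fold, FAM200C 9.94-fold and IL17RB, an interleukin-17 receptor, 8.06-fold. LCORL was 18.4-fold lower, IMMP2L, a mitochondrial peptidase, 13.9-fold, ARID1B 10.4-fold, BRWD1 9.99-fold and PRKCA, protein kinase C alpha, 9.05-fold. There 8692 genes were called, 5074 higher and 3618 lower. The interaction with estradiol was called in 7043 genes, 3749 positive and 3294 negative, led by CCNE2 (3.74, SE 0.19; limma, adjusted p = 3.85e-13), IL17RB (3.49), TP53I3 (3.38), SLC35G1 (3.04) and TMEM38A (2.77) and by LCORL (-3.63), IMMP2L (-3.61), ARID1B (-3.42), FBXL17 (-3.28) and DOCK1 (-3.24). The hypoxic ESR2 arrays in these comparisons are the ones with 3′ minus 5′ differences near 3.57.

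**Figure D5:**
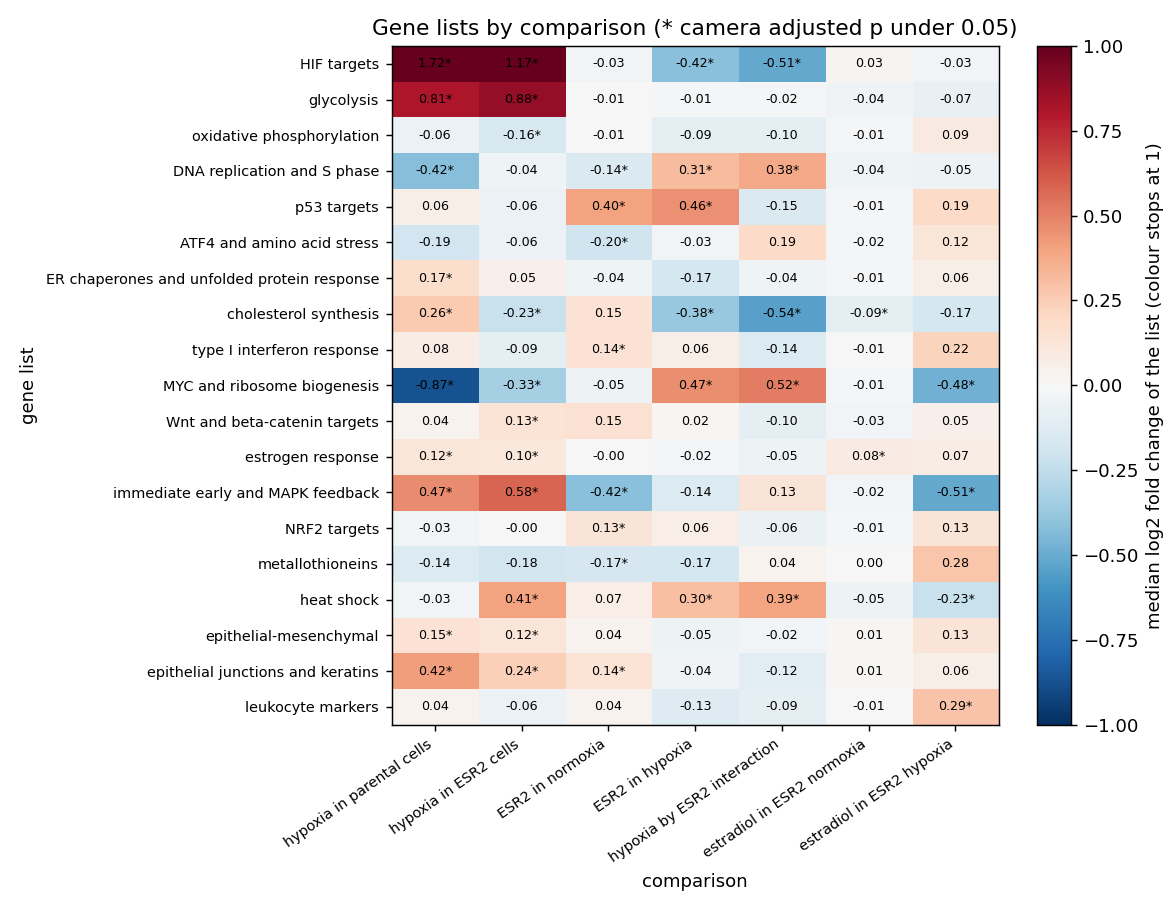
Median log2 fold change (colour and printed value) of 19 gene lists (y axis) in 7 comparisons (x axis), n = 3 arrays per group; a star marks a camera adjusted p under 0.05. HIF targets (1.72 and 1.17) and glycolysis (0.81 and 0.88) rose in hypoxia in both kinds of cells, while ribosome biogenesis genes had medians of -0.87 in parental and -0.33 in ESR2 cells.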

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

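The test of a response to estradiol through ESR2, that of uniformly weaker hypoxia, and the alternatives with the 3′ minus 5′ covariate or without arrays that stand apart were chosen after the result was seen.

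The difference of the hypoxia change between ESR2 and parental cells was past the threshold in 5597 genes without and 7043 genes with estradiol (limma). That of the estradiol change was past it in 4460 genes (limma), and rests mainly on the hypoxic ESR2 arrays with estradiol. Among lists the interaction median of hypoxia and ESR2 was -0.513 for HIF targets, 0.382 for DNA replication, -0.544 for cholesterol synthesis, 0.515 for ribosome biogenesis and 0.393 for heat shock (camera). The calls of HIF targets and of heat shock are lost with an estimated correlation (adjusted p = 0.0836 for each).

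Single genes with a positive interaction of hypoxia and ESR2 were DIDO1 at 3.076, NCOA5 at 3.017, MAT2A at 2.898, SLC35G1 at 2.627, FSAF1 at 2.428, WDR73 at 2.345, CCDC71 at 2.292, DLX2 at 2.272, CEBPA at 2.23 and RDH10 at 2.209. Negative ones were MAL2 at -2.566, OSMR at -2.407, KLF9 at -2.345, LCORL at -2.329, CXCL10 at -2.206, ZNF226 at -2.205, RSRP1 at -2.128, TRIOBP at -2.112, GASK1B at -2.078 and KRTAP4-9 at -2.075. Among list members they were CCNE1 at 1.305, GINS4 at 1.474, RRS1 at 2.055, NOP2 at 1.525, SERPINH1 at 1.999, DNAJA1 at 1.222, HILPDA at -1.641, ANKRD37 at -1.418, MSMO1 at -1.444, INSIG1 at -1.691 and HIF1A at -1.222.

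For the interaction of estradiol and ESR2 the values were 1.266 for AKR1B10, 1.082 for IRF7, 1.03 for VWA5A, 1.016 for CD68, 1.007 for ABHD14B, -1.867 for HIRA, -1.675 for ARID1B, -1.583 for LMNB1, -1.482 for GRB10 and -1.372 for MAGOHB. With estradiol, the interaction of hypoxia and ESR2 was 3.741 for CCNE2, 3.486 for IL17RB, 3.381 for TP53I3, 3.04 for SLC35G1, 2.773 for TMEM38A, -3.631 for LCORL, -3.609 for IMMP2L, -3.415 for ARID1B, -3.281 for FBXL17 and -3.235 for DOCK1.

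Control probe sets outside the gene comparisons gave a 3′ minus 5′ index with a mean of 3.741 (SD 0.301, n = 3) on the hypoxic ESR2 arrays with estradiol, against 2.103 (SD 0.0963, n = 3) on those without, and of 4.343 on replicate 2 of parental normoxia.

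A pattern to follow up is the number of genes that changed with estradiol in hypoxic ESR2 cells, 10394, against 0 in normoxic ESR2 cells (limma, 981 at an unadjusted p under 0.05); the difference between these was not tested. A higher background was tested by the calls among genes with a mean log2 signal over 6. Of these 69.2% were called, 4973 of 7189, with 2184 higher and 2789 lower. This does not decide, because quantile normalization can carry a narrowed range over to bright genes. A higher background therefore stays open for these and for the dimmer genes, of which 49.1% were called. Nonspecific control probe sets had a mean log2 signal of 2.96 to 3.01 on the hypoxic ESR2 arrays with estradiol. On those without estradiol it was 2.75 to 2.86. The upper quartiles of the log2 signal were 6.34 to 6.37 with estradiol and 6.51 to 6.60 without. With the 3′ minus 5′ index as a covariate 6897 genes were called, above the bound set for the test. That bound does not decide, because the index separates both groups completely, only replicate 2 of parental normoxia shares the high level, and without it the number is 4092, so that shorter labelled RNA and a change in the cells cannot be told apart for these genes. A response through ESR2 stays open as well, since r with the estradiol change of normoxic ESR2 cells was -0.008 across genes, which are not independent replicates, and a response limited to hypoxia would give no correlation.

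The other pattern is the smaller fall of ribosome biogenesis genes in hypoxic ESR2 cells without estradiol. A hypoxia change smaller by the same factor in all lists is argued against. The ratio of the hypoxia changes of ESR2 and parental cells differed between glycolysis (0.914) and ribosome biogenesis (0.398) by 6.46 standard errors. These errors were taken as independent, although both ratios come from the same arrays. Weaker hypoxia to which the lists respond unequally stays open, and the ratio for HIF targets was 0.705. With the 3′ minus 5′ covariate the median interaction was 0.511, or 0.579 without replicate 2 of parental normoxia. This does not decide on shorter labelled RNA, because the slope of the covariate rests on differences within groups, mostly on that array. Replicate 2 of parental normoxia alone as the cause is argued against by a median of 0.575 without it. With estradiol the median fall was nearly as large in ESR2 (-0.75) as in parental cells (-0.935), and the interaction was not called (13 higher, 4 lower and 17 not passing, 13 and 4 adjusted over the list alone, median 0.05, camera, adjusted p = 0.335), on hypoxic ESR2 arrays that have the high 3′ minus 5′ index. A difference between the cells without estradiol stays open as a hypothesis found on the same arrays, while its dependence on estradiol, and whether it follows ESR2 or the lentiviral transduction and puromycin selection, were not tested.

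Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. All but the real one mix arrays of both compared groups, which widens the spread where the groups differ. Their low counts are therefore no evidence against chance. In each of the following the real split was the 1 with the largest count, given with the highest of the others: hypoxia in parental cells 6844 and 1, hypoxia in ESR2 cells 5940 and 2, ESR2 in normoxia 3396 and 108, ESR2 in hypoxia 7369 and 0. Estradiol gave 2 and 0 in parental normoxia, 3 and 1 in parental hypoxia and 10394 and 1 in ESR2 hypoxia. In ESR2 normoxia all 10 splits gave 0. With estradiol the counts were 6345 and 0 for hypoxia in parental cells, 9534 and 1 in ESR2 cells, and 2494 and 0 for ESR2 in normoxia and 8692 and 0 in hypoxia.

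For interactions 100 splits were drawn. Most of them mix arrays of groups that differ strongly, which widens the spread and lowers the count. A share under 0.05 therefore does not exclude chance. As many genes as the real split were called, the real split included, by 2 of 100 for hypoxia and ESR2 (real 5597, highest other 6271, a split that exchanges a whole pair of groups; 4920 without it), by 3 of 100 for estradiol and ESR2 (4460 and 4901), and by 1 of 100 with estradiol (7043 and 6108). The median of the other splits was 0 in each.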

How the results depend on the processing

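The covariate alternatives and that without arrays that stand apart were chosen after the data were seen. Of 6190 values of named genes under alternatives, 6117 kept their direction and side of the threshold and 73, of 22 of 319 results, did not; of 1799 values of called lists 1685 did, and 114, of 44 of 89 calls, did not. An estimated correlation ended 40 of the 89. Genes called for estradiol in parental normoxia (2) numbered 1 with quantile normalization, the mean of probe sets or a trend and robust prior, 604 with array weights, and 0 with every probe set, only the groups compared, the covariate (with or without replicate 2) or without the arrays that stand apart. In parental hypoxia (3) they numbered 12 with every probe set, 59 with array weights, 1 with only the groups compared and 9 without the arrays that stand apart. In ESR2 normoxia (0) they numbered 1 with quantile normalization, centring, the mean of probe sets, a trend, only the groups compared or the covariate, 5 with array weights and 4 without the arrays that stand apart. ESR2 in normoxia (3396) gave 5187 with array weights and 1061 with only the groups compared, and with estradiol (2494) 4437 and 3772. Estradiol in ESR2 hypoxia (10394) gave 6897 with the covariate and 4092 without replicate 2 as well, and the interaction of estradiol and ESR2 (4460) 2870 under the latter. The more frequent direction of the calls also turned in these cases. For ESR2 in hypoxia 3530 were higher and 3952 lower with the mean of probe sets, 4320 and 5146 with array weights, 4180 and 4336 without the arrays that stand apart, and 3683 and 4076 without hypoxic ESR2 replicate 3. With every probe set 4687 genes had a higher and 5141 a lower probe set, some of them both. For ESR2 in normoxia it was 1956 and 1968 without parental replicate 1 and 1695 and 1713 without replicate 3. Array weights gave 3577 and 3958 for the interaction of hypoxia and ESR2 and 3399 and 3025 for that of estradiol and ESR2. For hypoxia in ESR2 cells the covariate without replicate 2 gave 2671 and 2649. With estradiol, leaving out the dimmest genes gave 3915 and 4063 for hypoxia in ESR2 cells and 3168 and 3254 for the interaction. The covariate, with and without replicate 2, gave 4016 and 4125, and 3008 and 3568, for the former, and 3062 and 3389, and 2674 and 3054, for the latter. Without replicate 2 it gave 2907 and 3030 for ESR2 in hypoxia with estradiol. For the interaction of estradiol and ESR2 it left 34% of calls positive, or 31.7% without replicate 2, against 47.3%. Leaving out 1 array gave 6205 to 6843 for hypoxia in parental and 4699 to 6328 in ESR2 cells, 2383 to 3924 for ESR2 in normoxia and 6127 to 7759 in hypoxia, 4997 to 5817 for their interaction, 8846 to 10573 for estradiol in ESR2 hypoxia and 3967 to 5004 for its interaction. With estradiol these were 5748 to 5805, 8401 to 9043, 1675 to 2130, 7863 to 8347 and 6364 to 6881. For estradiol in parental normoxia the range was 0 to 643 (0 without untreated replicate 2, 643 without replicate 1), in parental hypoxia 1 to 3 and in ESR2 normoxia 0 to 1 (1 without untreated replicate 3 or estradiol replicate 1). The sign of ESR2 itself, never called there, turned for estradiol in parental normoxia (-0.03) to 0.007 with the mean of probe sets, 0.077 and 0.027 with the covariate with and without replicate 2, and 0.004 without the arrays that stand apart, with a range of -0.092 to 0.049 on leaving out 1 array. In parental hypoxia (0.042) it was -0.044 with the covariate without replicate 2 and -0.02 to 0.09 on leaving out 1 array, and in ESR2 normoxia (-0.101) -0.343 to 0.085. The cause was not tested.

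The replicate number as a block gave 0 genes for estradiol in parental normoxia and 1 in ESR2 normoxia, and moved no other count by over 1.5 times. It also ended the calls of MT1F, KLC3, KIN and the ATF4 and metallothionein lists for estradiol in parental cells. No pairing by number was seen, though a weak one is not excluded. Same-number arrays correlated at -0.288 to 0.287 and 7 of 24 arrays correlated best with their own number. Arrays hold signal over background, not counts, and dim genes have compressed changes.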

Other observations

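The test of long genes was set before its result was seen, while the covariate it uses was chosen after the data were seen. With estradiol in both conditions, hypoxia in parental cells raised 32 of 37 HIF targets (5 did not pass; 32 adjusted over the list alone, median 1.74, camera, adjusted p = 5.37e-33) and all 22 glycolysis genes (22 adjusted over the list alone, median 0.87, adjusted p = 4.09e-19). It lowered 32 of 34 ribosome biogenesis genes (1 rose; 32 and 1 adjusted over the list alone, median -0.94, adjusted p = 4.41e-20). In ESR2 cells with estradiol 30 of 37 HIF targets rose, 2 fell and 5 did not pass (31 and 2 adjusted over the list alone, median 0.99, camera, adjusted p = 1.45e-12). Of 34 ribosome biogenesis genes 29 fell and 5 did not pass (29 adjusted over the list alone, median -0.75, adjusted p = 4.09e-13). Fatty acid synthesis genes fell in 9 of 14, rose in 2 and did not pass in 3 (9 and 2 adjusted over the list alone, median -0.27, camera, adjusted p = 0.012, and adjusted p = 0.136 with an estimated correlation). Without the dimmest genes that call ends as well (adjusted p = 0.0808). The arrays of hypoxic ESR2 cells with estradiol are those with a high 3′ minus 5′ index.

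In normoxia with estradiol, ESR2 cells had higher p53 targets, 13 of 26 with 1 lower and 12 not passing (14 and 1 adjusted over the list alone, median 0.27, camera, adjusted p = 1.91e-10). Interferon genes were higher in 13 of 35 with 22 not passing (15 adjusted over the list alone, median 0.21, adjusted p = 4.79e-08), and NRF2 targets in 9 of 23 with 14 not passing (12 higher and 1 lower adjusted over the list alone, median 0.22, adjusted p = 4.19e-05). In hypoxia with estradiol cholesterol synthesis genes were lower in 13 of 20, higher in 1 and did not pass in 6, also adjusted over the list alone (median -0.46, camera, adjusted p = 8.78e-06). The interaction of hypoxia and ESR2 with estradiol was negative for 13 of 20 cholesterol genes, positive for 1 and not past the threshold for 6 (14 and 1 adjusted over the list alone, median -0.65, camera, adjusted p = 3.21e-06). For HIF targets it was negative in 25 of 37, positive in 3 and not past the threshold in 9, also adjusted over the list alone (median -0.84, camera, adjusted p = 7.48e-09, and adjusted p = 0.0897 with an estimated correlation).

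Some lists were not called for hypoxia in parental cells. Of 37 mitosis genes 9 rose, 16 fell and 12 did not pass (9 and 17 adjusted over the list alone, camera, adjusted p = 0.0716). NF-kB and cytokine genes gave 3 rises and 6 falls of 26, also adjusted over the list alone (adjusted p = 0.813), and fatty acid synthesis 5 and 3 of 14 (6 and 3 adjusted over the list alone, adjusted p = 0.594). Enterocyte and goblet genes gave 2 and 2 of 32 (1 and 2 adjusted over the list alone, adjusted p = 0.774). Fibroblast markers gave 1 rise of 14 (adjusted p = 0.813) and embryonic kidney line markers 1 rise and 1 fall of 13 (adjusted p = 0.883), both also adjusted over the list alone. With estradiol in hypoxic ESR2 cells enterocyte and goblet genes rose in 17 of 32, fell in 2 and did not pass in 13 (18 and 2 adjusted over the list alone, median 0.21, camera, adjusted p = 0.0632).

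A hypothesis is that the fall of long genes with estradiol in hypoxic ESR2 cells reflects something other than shorter labelled RNA, which may lower signal far from the 3′ end. With the 3′ minus 5′ index as a covariate the median change of the 82 genes over 400 kb with a mean log2 signal over 6 was -1.017, and -0.97 without replicate 2 of parental normoxia, against -0.96 without the covariate. This does not decide on RNA length, because the index separates the hypoxic ESR2 arrays with and without estradiol completely. Its slope rests mostly on replicate 2 of parental normoxia. Per array the median deviation of these genes from their mean lay between -1 and -0.91 on the hypoxic ESR2 arrays with estradiol, and -0.01 on replicate 2 of parental normoxia, which has the highest index. On the hypoxic parental arrays it lay between 0.39 and 0.51, and on the hypoxic ESR2 arrays without estradiol between -0.14 and 0.06. The mean index of the latter was 2.103, against 2.357 on hypoxic parental arrays without estradiol. The median hypoxia change of these genes in parental cells was 0.51 without and 0.45 with estradiol. In ESR2 cells without estradiol it was -0.13. No biological explanation was tested.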
